A study of Mus musculus with 2 samples.

How the data were processed

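DNase-seq data of mouse adrenal gland were analysed from 2 samples, biological replicates 1 and 2 of 1 group per the labels. The labels give females of an F1 cross of C57BL/6J and CAST/EiJ, 10 days of age, with 3 females named per sample. Per the deposited file listing, every file was made from the alignments of 1 sample on the mouse build mm10, with no pooling of replicates. The aligner, the peak caller and the footprint caller are not given in the sources used here. Each sample had 2 peak lists, a footprint list and a list of FDR values.

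The peak height is a signal that the authors normalised, and it is given once per peak. In each deposited list 100.0% of the signal values were whole multiples of 1 step per sample within 5% of a step (0.00668 in replicate 1 and 0.00620 in replicate 2). If each step were 1 tag on 1 common scale, the total of replicate 1 would be 0.927 times that of replicate 2. That reading is inferred from the values, so neither this ratio nor the counting error is a stated depth. The deposited FDR values are p-values after adjustment, given per stretch of bases and listed under 0.05. In the shorter peak list every peak held a base at an FDR of at most 0.001 and in the longer list at most 0.05. The footprint lists carry the same deposited p-value of 0.01 for each footprint, which was read as the threshold of the call. Reads from the CAST/EiJ alleles were placed on mm10, which can lower signal where the strains differ. Read depth per sample was not used here beyond the counts of peaks, footprints and bases above.

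The shorter peak list (98813 and 55135 peaks) served as the main list and the longer one (159343 and 93845) as an alternative. This choice was made after the structure of the lists had been seen and before any result. Shared peaks were merged regions holding peaks of both replicates with at least 1 bp of overlap, and heights were the highest in each replicate. Overlap was set beside 20 circular shifts along each chromosome. Genes and starts came from GENCODE release M21 and sequence from the mm10 reference, and 0 peaks or footprints ended beyond a reference chromosome. A promoter was the 1 kb on each side of any annotated start of a protein-coding gene, and distal peaks lay more than 1 kb from every annotated start.

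The 23 gene lists (376 entries), the 32 motif consensuses, the tests and the naming rule were fixed before the data were examined. For promoters, the share of a list with a shared peak was set beside 10000 random lists of the same size matched on the decile of CpG observed over expected within 500 bp of the start. For distal sites, the number of shared distal peaks within 50 kb of the most 5' start was set beside lists matched on the decile of neighbouring starts. For the replicate difference, the mean log2 ratio of shared peaks within 50 kb was centred on the median of all shared peaks, and the median over the list was set beside random lists. A list was called when it lay outside the central 95% of its random lists. With 3 tests of 23 lists each, some calls arise by chance, and on simulated data 5.0% of 200 null lists were called with CpG matching, against 24.0% without.

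Named genes were chosen by the fixed rule: for each list up to 4 members with the highest promoter peaks and up to 2 without a promoter peak, every member of the steroidogenesis and chromaffin lists as needed, genes among the 10 with the most distal peaks, and the 10 highest distal peaks. Further names (Nr5a1, Arntl, Adipoq, Tbr1, the members with high numbers of distal peaks and those with large replicate ratios) were chosen after their values were seen. Where another gene's start lay within 1 kb of a named gene's highest promoter peak, that gene is stated beside it.

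Motif matches were counted on either strand within 75 bp of the centre of distal peaks, and in 1 window per peak of the same width, drawn outside all peaks and matched on GC content in bins of 2.0%. Mean GC content was 54.1% in peaks and 54.0% in windows. Folds carry exact conditional 95% intervals, and a motif was called enriched when its interval lay above 1, a criterion added to the fixed design. Where the windows held 0 matches, the lower limit of the interval is given, and a value with a floor of 3 counts served only to compare settings. These intervals replaced log-scale intervals after a first run in which REST and NFI had given no fold. Footprint coverage was the share of match centres inside a footprint, set beside 10 column-permuted versions of each consensus, with exact binomial intervals, and was called when the intervals did not overlap. Ratios by motif used 1000 bootstrap draws of peaks and the list contrast 2000 draws of genes. Ratios by motif, motifs in the peaks of 1 replicate only, single matches in promoters and near genes, the list and motif pairs, starts of neighbouring genes and a second adipocyte list were added after the data had been seen.

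On simulated data, planted overlaps of 19.9%, 50.1% and 90.0% of 98813 peaks were recovered as 20.3%, 50.8% and 90.3%, and planted lists of high promoter share were called in 100.0% of 200 draws. Planted motif shares of 5.16% (NR5A), 4.86% (AP-1) and 5.09% (CTCF) in 20000 sequences were recovered as an excess of 5.40%, 4.98% and 5.11%.

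Alternatives covered reciprocal overlap of 50%, peak centres within 75 bp, the 50% highest peaks of each list, equal list lengths, the longer lists, promoters of 500 bp and 2 kb, the most 5' start only, unmatched random lists, windows of 25 and 100 kb, ranks in place of log2 ratios, motif windows of 150 bp, flanking sequence as background, footprints in shared peaks, promoter peaks in place of distal ones, and each replicate on its own. Added after seeing the data were centring within 20 bins of height, CpG-matched lists with that centring, distal peaks only, genes with a promoter peak only, windows matched on CpG dinucleotides, and overlap with any base under FDR 0.05. No test between conditions was made, since there was 1 group, and the constant score and summit columns of the peak lists were not used. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.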

Results

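Open chromatin was mapped by DNase-seq in the adrenal gland of female mice aged 10 days. In this assay, nuclei are treated with the enzyme DNase I and the ends it leaves in accessible DNA are sequenced. The mice were first-generation offspring of the strains C57BL/6J and CAST/EiJ, and each sample carried a label of 3 females. The adrenal gland holds a cortex that makes steroid hormones, a medulla of chromaffin cells that make catecholamines, and a capsule around them. There was 1 group of 2 biological replicates, so the data gave no comparison between conditions, and the comparisons were between the replicates, between gene groups and between sequence motifs. Replicate 1 had 98813 peaks at a false discovery rate (FDR) of 0.001, 339116 footprints (short protected stretches inside open chromatin) and 51.5 Mb listed at an FDR under 0.05. Replicate 2 had 55135 peaks, 241536 footprints and 34.0 Mb. Read totals were not used here, and peak heights were whole multiples of a step per sample, so the median height of 1.04 in replicate 1 and 1.06 in replicate 2 stood for 156 and 171 steps. If each step was 1 sequenced tag, the counting error at the median height was 8.01% and 7.65%. Percentiles among random lists are descriptions of these libraries and no p-values, and genes and peaks are not replicates. The exact intervals cover counting error only, and the bootstrap intervals cover the spread between genes or between peaks. None of them covers variation between animals.

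The accessible sites of replicate 2 were largely a subset of those of replicate 1. Of the replicate 2 peaks, 91.5% overlapped a peak of replicate 1 by at least 1 bp, and 51.9% of the replicate 1 peaks overlapped a peak of replicate 2. After circular shifts along each chromosome these shares were 1.64% and 0.904%. The overlaps gave 48299 shared peaks, whose heights ranked alike in both replicates (Spearman correlation 0.910, Pearson r on the log2 scale 0.927, across peaks). Shared peaks were higher in replicate 1, by a median of 0.73 on the log2 scale, or 1.66-fold, and 93.0% of them were higher there. The median log2 ratio of replicate 1 over replicate 2 was 0.32 in the lowest decile of height and 1.13 in the highest. The 47541 peaks found only in replicate 1 had a median height of 0.682, and 17.4% of them lay at promoters. The 4711 peaks found only in replicate 2 had a median height of 0.514, and 48.3% lay at promoters. With both lists at equal length the shares were 76.2% of replicate 1 and 75.4% of replicate 2, and 78.1% of the replicate 1 peaks held a base at an FDR under 0.05 in replicate 2, a comparison chosen after seeing the data.

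Shared peaks were concentrated at promoters. Of them, 44.9% lay within 1 kb of an annotated transcription start site (TSS), 25.4% in introns, 26.0% between genes and 3.79% in exons, against 6.82%, 37.9%, 52.3% and 2.93% after circular shifts. Promoter peaks were higher than distal ones, with median heights of 3.21 and 1.95 in replicates 1 and 2 against 1.497 and 0.874. Chromosome 11 was the most densely covered autosome, with 59.5 peaks per Mb in replicate 1 and 36.6 in replicate 2, and chromosome 3 the least, with 30.7 and 16.1. The X chromosome held 13.6 and 7.82 peaks per Mb, which was 34.8% and 35.8% of the density of all autosomes. On the Y chromosome, replicate 1 had 15 peaks and replicate 2 had 11, or 0.163 and 0.120 per Mb, in animals labelled female. The highest Y peak of replicate 1 lay at chromosome Y 90744501 to 90744860 (mm10, height 2.39) and that of replicate 2 at 90744601 to 90744820 (height 5.91).

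Promoters of the steroid hormone pathway were open more often than promoters of the same CpG content. A shared promoter peak was found for 13 of 18 steroidogenesis genes (72.2%, against a mean of 43.5% and a central 95% of 27.8% to 55.6% for matched random lists). The highest were Por, the electron donor of microsomal P450 enzymes (14.0 in replicate 1 and 5.89 in replicate 2), Fdxr, the reductase that feeds mitochondrial P450 enzymes (11.1 and 4.30), the cholesterol transfer protein gene Stard4 (9.98 and 3.91) and the lipase gene Lipe (8.82 and 4.78). Scarb1, the receptor that takes up cholesterol from high-density lipoprotein, had 8.16 and 4.92, and Fdx1, the ferredoxin of mitochondrial P450 enzymes, 6.87 and 3.73. Star, which brings cholesterol into mitochondria, had 3.58 and 1.28, Akr1b7 2.30 and 0.911, and Cyp11b1, the 11beta-hydroxylase, 1.51 and 0.812. Mrap, the accessory protein of the corticotropin receptor, had 5.23 and 2.14, Soat1, which esterifies cholesterol, 6.03 and 3.07, and Hsd3b6 0.655 and 0.360. The peak of Cyp11a1, the enzyme that cleaves the cholesterol side chain, lay at chromosome 9 58014881 to 58015120, within 210 bp of an internal annotated start and inside the gene, with heights of 3.74 and 1.87. The 21-hydroxylase gene Cyp21a1 (height 2.21) and the corticotropin receptor gene Mc2r (0.802) had a promoter peak in replicate 1 only. The aldosterone synthase gene Cyp11b2, Hsd3b1 and Sult1e1 had none. The list stood at percentile 99.995 of the matched random lists, at 97.2 when only the most 5' start of each gene was used, which ended the call, and at 77.96 against random lists not matched on CpG content, which ended it as well.

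Most regulators of the cortex and all genes of cholesterol synthesis had open promoters. Of 25 cortex transcription factor and signalling genes, 22 had a shared promoter peak (88% against 91.4% in matched lists, percentile 25.4), among them Cited2 (13.0 and 8.56), Creb1 (13.0 and 6.96), Nr4a1 (11.95 and 5.13) and Znrf3 (10.4 and 5.45). Nr5a1, which encodes the steroidogenic factor SF-1, had 3.24 and 2.10, at chromosome 2 38714401 to 38714640, and Tcf21, a factor of capsular cells, had none. Against lists not matched on CpG content this group lay at percentile 99.7 and was called higher. Of 13 zonation genes, 9 had one (percentile 94.99), led by the potassium channel gene Kcnk3 (6.56 and 4.15), the angiotensin receptor gene Agtr1a (4.49 and 2.32), Thrb (4.43 and 2.24) and Dab2 (4.42 and 2.10), and Pik3c2g had none. The zonation list was called higher at 2 kb around the TSS (98.5) and on all peaks of replicate 2 (99.3). All 22 cholesterol genes had one, against 92.9% in matched lists, whose central 95% reached 100%, so that this list could not be called higher. In the 50% highest peaks all 22 kept one, against 85.2%, and the list was called higher (percentile 98.7). The highest promoter peaks were those of Dhcr7 at 16.8 and 6.37, Insig1 at 15.3 and 6.56, Npc1 at 14.6 and 5.43 and Mvd at 13.6 and 4.44. The Dhcr7 peak also lay within 1 kb of a start of Nadsyn1. Against all genes, the cholesterol list was called higher (percentile 99.99).

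Chromaffin genes had shared promoter peaks about as often as CpG-matched genes. They were found for 20 of 28 (71.4% against 79.0% in matched lists, percentile 10.9), with median heights of 1.62 and 1.21 over the members with a peak, against 5.23 and 3.07 in the steroidogenesis list. The vesicular amine transporter gene Slc18a1 (13.7 and 6.86) led, but its peak also lay within 1 kb of a start of Atp6v1b2. Next came Chgb, which encodes a secretory granule protein (8.31 and 4.17), Gata3 (7.08 and 3.18) and Gch1 (6.404 and 3.17). Gata2 had 5.395 and 2.78, Isl1 3.33 and 1.46, Scg2 3.10 and 1.78, Chga 2.20 and 1.84, and Dbh, which converts dopamine to noradrenaline, 1.12 and 0.570. Th, the first enzyme of catecholamine synthesis, had a promoter peak in replicate 1 only (0.809), as had Hand2 (1.22). Slc18a2 (0.527) and Chrnb4 (0.558) had one in replicate 2 only, and Ddc and Pnmt, the enzyme that makes adrenaline, had none. In the 50% highest peaks of each replicate only 13 chromaffin genes kept a shared promoter peak, and the list was called lower (percentile 0.080).

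Adipocyte, capsule and clock genes were also open more often than their CpG-matched controls. Shared promoter peaks were found for 13 of 14 adipocyte genes (92.9% against 46.7%, above all 10000 random lists), including Cebpa (11.8 and 6.82), Cidea (3.12 and 1.87), Plin4 (3.04 and 1.78), and Ucp1, the uncoupling protein of brown fat (2.58 and 2.01). The exception was Adipoq, with a peak of 1.27 in replicate 1 only. Of 16 capsule and fibroblast genes, 12 had one (75% against 43.4%, percentile 99.95), with Pdgfra at 4.69 and 3.19, Col1a1 at 3.42 and 2.72, Twist1 at 2.22 and 1.65, and Fbn1 at 2.03 and 1.70. The Fbn1 peak also lay near a start of Gm9913, and Lum and Mgp had no promoter peak. This call ended against unmatched lists (82.6), and in the 50% highest peaks the list lay at percentile 35.2. All 17 circadian clock genes had one (against 87.4% in matched lists, percentile 99.2), with Tef at 16.3 and 6.26, Nr1d1 at 14.1 and 5.81, Per1 at 12.3 and 6.15, and Arntl at 9.86 and 3.48.

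Kidney, germ cell and skeletal muscle genes had shared promoter peaks less often than CpG-matched genes. The counts were 2 of 15 kidney genes (13.3% against 37.5%, percentile 0.20), 1 of 12 germ cell genes (8.33% against 52.4%, percentile 0) and 3 of 14 skeletal muscle genes (21.4% against 47.1%, percentile 1.0). Among kidney genes Lrp2 had heights of 0.421 and 0.502, and Umod and Slc12a1 had no such peak. The germ cell gene was Dazl (8.01 and 3.31), and Ddx4 and Sycp3 had none. In muscle they were Ckm (2.16 and 0.930), Mylpf and Actn3, and the peaks of Mylpf and Actn3 also lay near starts of Tbc1d10b and Zdhhc24. On all peaks of replicate 2 the kidney and muscle calls ended (percentiles 9.67 and 13.3), and the muscle call also ended at 2 kb (3.14).

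The remaining 12 lists were not called in the main setting. Among blood markers, 0 of 15 myeloid genes (15.6% in matched lists), 2 of 15 lymphocyte genes (Pax5 and Tcf7, 13.3% against 30.3%) and 4 of 12 erythroid genes (among them Nfe2, Epor and Tal1, 33.3% against 27.4%) were open. The lymphocyte list was called lower with the most 5' start only (percentile 0.43) and on all peaks of replicate 2 (2.00). Spi1 and Cd68 had promoter peaks of 1.20 and 1.14 in replicate 1 only, and the globin genes Hbb-bt and Hbb-bs had none. Of 14 liver genes 1 was open (Apob), and Alb and Apoa1 were not, and the list was called lower at 500 bp (0 of 14, percentile 2.07). Shared promoter peaks were found for 9 of 16 endothelial genes, with Flt1 at 2.81 and 1.66 and none at Pecam1 and Cdh5. They were found for 10 of 14 Schwann and sustentacular genes, with none at Sox10. The counts were 6 of 13 gonad genes, with Sox9 at 3.94 and 1.87, and 9 of 14 brain neuron genes. The brain neuron list was called lower at 500 bp (6 of 14, percentile 0.030), with the most 5' start only (6 of 14, percentile 0.21) and in the 50% highest peaks (3 of 14, percentile 0), where the endothelial list was lower too (4 of 16, percentile 1.23). All 19 immediate early, 18 cell cycle and 17 housekeeping genes were open, shares that their random lists reached as well, and 14 of 15 glucocorticoid response genes, the exception being Tat. The glucocorticoid response list was called higher in the 50% highest peaks (98.2). Among the highest were Ddit4 (17.1 and 6.81), Actb (16.1 and 7.27), Jun (15.7 and 5.45) and Ccna2 (14.5 and 5.19). Across all 21646 protein-coding genes 63.1% had a shared promoter peak, from 2.22% in the lowest decile of CpG content to 98.5% in the highest.

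**Figure D1:**
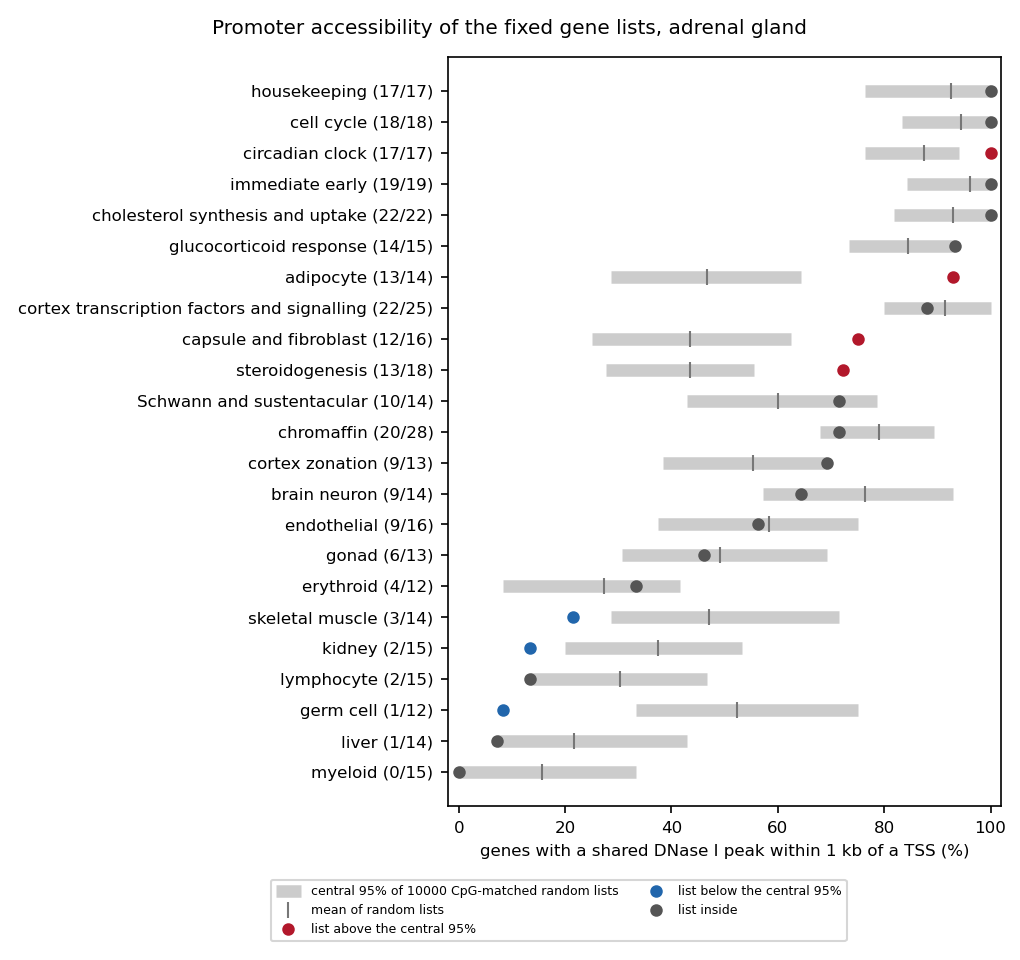
Share of genes in each of the 23 fixed lists with a DNase I peak of both replicates within 1 kb of a TSS (points, in %), with the counts beside the list names. Grey bars span the central 95% of 10000 random lists matched on promoter CpG content and ticks mark their mean; red lists (4) lie above, blue lists (3) below.

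Immediate early, glucocorticoid response and circadian clock genes had more distal accessible sites around them than other genes. Within 50 kb of the most 5' TSS, immediate early genes had 4.26 shared distal peaks per gene against 1.56 in lists matched on gene density. Among them, Fosb and Gadd45b had 9 and Nr4a1 had 8. Glucocorticoid response genes had 4.27 against 1.56, with 11 at Ddit4, 10 at Per1, 8 at Pck1, a gene of gluconeogenesis, and 7 at Klf15. Circadian clock genes had 3.71 against 1.60, with 10 each at Nr1d1 and Per1 and 5 each at Arntl, Per2 and Cry2. Per1 belonged to both the glucocorticoid response and the clock list, and Dusp1 to both the immediate early and the glucocorticoid response list. Their results are therefore not fully separate. The immediate early and glucocorticoid lists lay above all 10000 random lists, and the clock list at percentile 99.995. The other 20 lists were not called, including steroidogenesis (1.72 against 1.60, percentile 63.8), chromaffin (1.5 against 1.49, percentile 53.7), adipocyte (2.36 against 1.55, percentile 94.4) and cortex regulators (1.92 against 1.42, percentile 92.1). On all peaks of replicate 1, steroidogenesis genes had 6.17 distal peaks against 3.60 (percentile 99.9), and that list was then called higher, whereas on all peaks of replicate 2 they had 2.22 against 1.80 (percentile 80.8). Cortex regulators were called higher in each replicate on its own (98.8 and 99.7). Adipocyte genes were called higher on all peaks of replicate 1 (5.79 against 3.54, percentile 99.0) and within 100 kb (98.2). Housekeeping genes (2.71 against 1.73, percentile 97.4 in the main setting) were called higher within 25 kb (98.3), against unmatched lists (98.7) and in the 50% highest peaks (99.2), and cell cycle genes within 100 kb (98.97) and in the 50% highest peaks (97.9), as were cortex regulators there (99.4).

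By number of distal peaks, the leading genes over the genome included Tmem107 with 17, the neuromedin receptor gene Nmur1 and the retinoic acid receptor gene Rara with 16 each, the histone demethylase gene Kdm6b with 14, and Btn1a1, Kcnk3, Dhx37 and Id1 with 13 each. The median over all genes was 1. The highest distal peak lay in an exon 7111 bp from the nearest start, of Lars2, at chromosome 9 123461901 to 123462100 (54.6 and 45.7). It was followed by chromosome 6 49236421 to 49236620, between genes and nearest to Igf2bp3 (38.9 and 30.0), and chromosome 15 99735641 to 99735920, in an exon near Cox14 (22.2 and 34.0). Ranks 4 to 10 were nearest to Il31ra (29.9 and 25.2), Gm8797 (21.9 and 18.7), Gm21887 (26.9 and 13.0), Jarid2 (20.6 and 18.6), Pak3 (23.3 and 15.9), Gphn (15.7 and 13.1) and Ubqln1 (11.3 and 16.9). The peaks near Cox14 and Ubqln1 were higher in replicate 2, unlike 93.0% of all shared peaks.

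Relative to all shared peaks, peaks near steroidogenesis and cholesterol genes leaned towards replicate 1, and peaks near chromaffin genes towards replicate 2. Log2 ratios of replicate 1 over replicate 2, centred on the median of all shared peaks, were higher near steroidogenesis genes (median 0.18 over 18 genes, percentile 99.0) and cholesterol genes (0.19 over 22, percentile 99.8), and lower near chromaffin genes (-0.23 over 26, percentile 0.030). Among steroidogenesis genes, the means per gene were 0.62 at Stard4, 0.46 at Cyp11a1, 0.42 at Star and 0.41 at Mrap, and among cholesterol genes 0.41 at Dhcr7. Among chromaffin genes they were -0.56 at Chrna3, -0.55 at Slc18a2, -0.47 at Phox2a, -0.32 at Pnmt and -0.30 at Chga, while Isl1 had 0.45 and Chgb 0.44. Brain neuron genes were also lower (-0.27 over 14, percentile 0.090), with -0.62 at Tbr1, and cell cycle (0.19, percentile 99.6) and clock genes (0.17, percentile 98.2) were higher. The chromaffin minus steroidogenesis difference of medians was -0.41 (95% bootstrap interval over genes -0.64 to -0.21). Because the ratio rose with peak height, it was recomputed after centring within bins of height, an alternative chosen after seeing the data, and was then -0.34 (-0.51 to -0.14). Both bootstraps drew genes as if independent, although members with overlapping windows share peaks, so these intervals may be too narrow. The random lists were not matched on such closeness of members either.

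With that centring, steroidogenesis, cholesterol and chromaffin kept their calls (percentiles 99.99, 98.1 and 0.78), those of brain neuron (3.21), cell cycle (90.2) and clock genes (93.6) ended, and zonation (0.12, percentile 98.5) and adipocyte genes (-0.17, percentile 1.54) were called higher and lower. With ranks in place of log2 ratios, steroidogenesis (100), cholesterol (98.8) and zonation (98.6) were called higher and chromaffin (0.11) and brain neuron (1.79) lower, and cell cycle (93.9) and clock genes (93.7) were not called. With distal peaks only and the same centring, none of these lists was called, on fewer genes and with wider random intervals. The medians were then -0.11 over 20 chromaffin genes (percentile 6.06) and 0.14 over 13 steroidogenesis genes (percentile 87.8), against -0.15 over 26 and 0.19 over 18 with all peaks. With log2 ratios centred on the overall median again, in a window of 100 kb the higher calls ended, with steroidogenesis at 96.9 and cholesterol at 90.1. In a window of 25 kb the cholesterol (95.6) and clock (94.5) calls ended. Further lower calls were those of kidney (0.22) and gonad genes (0.61) within 25 kb and of endothelial (0.40), liver (0.97) and kidney genes (1.64) within 100 kb.

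Distal accessible sites were rich in the recognition sequences of CTCF, AP-1 and nuclear receptors. Of 26615 shared distal peaks, 3544 (13.3%) held a match to the CTCF consensus CCASYAGRKGGC within 75 bp of their centre, against 15 of as many GC-matched windows, a 236-fold enrichment (95% interval 143 to 423). REST, the repressor of neuronal genes, had 132 matches against 0 (lower 95% limit 35.3-fold), and NFI 45 against 0 (lower 95% limit 11.7-fold). C/EBP followed with 10.8-fold (3.91 to 41.2), RFX with 6.36-fold, MEF2 with 4.67-fold, NRF1 with 3.67-fold, AP-1 with 2.82-fold (1653 peaks, 2.57 to 3.10), the steroid receptor element with 2.32-fold (1.32 to 4.2) and the cAMP response element CRE with 2.27-fold (1.55 to 3.36). The NR5A consensus, bound by SF-1, was found in 1054 peaks (3.96%) against 518 windows, or 2.03-fold (1.83 to 2.26), and the NBRE of the NR4A factors in 325 against 146, or 2.23-fold. An interval above 1 was found for 26 of 32 consensuses and an interval below 1 for 0. The least enriched were SREBP (0.910, 0.736 to 1.12), GATA (996 peaks against 994 windows), the E-box CAGATG (1.09, 1.04 to 1.14), NFY (1.10) and FOX (1.23).

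Several motifs depended on the replicate or the background. On the distal peaks of replicate 1 alone, NR5A was enriched 3.39-fold (3.18 to 3.62) and AP-1 4.93-fold, against 1.88-fold and 2.65-fold on those of replicate 2 alone. CTCF was enriched 122.3-fold (89.0 to 173) on replicate 1 alone and 137-fold (93.4 to 210) on replicate 2 alone, with a match in 6.98% and 12.04% of the peaks and 0.0571% and 0.0879% of the windows, against 13.3% and 0.0564% in the main setting. NFI was enriched 26.0-fold and 9.20-fold. Against sequence 500 bp away from the same peaks, GATA fell to 0.670, TCF/LEF to 0.789, IRF to 0.790, PBX-HOX to 0.755 and FOX to 0.784, all with intervals below 1. These flanks were not matched on GC content, so a difference in base content was not separated from depletion of the motifs. CTCF was enriched 86.4-fold there, NFI 10.0-fold (4.83 to 23.3), MEF2 1.54-fold and C/EBP 4.09-fold. With this background 20 consensuses were called enriched, against 26 in the main setting, and the steroid receptor element was among those no longer called (1.49). On replicate 2 alone the steroid receptor element was not called either (1.62), and RFX was enriched 3.10-fold. With matches counted within 150 bp, C/EBP was enriched 6.75-fold, MEF2 3.09-fold and RFX 2.83-fold, and the E-box CAGATG lost its call. Against windows matched on GC and CpG content, a background chosen after seeing the data, CTCF was enriched 148-fold (99.1 to 231), ETS was no longer called (1.10, 0.843 to 1.43, against 1.74), and 25 consensuses were enriched. In the 50% highest peaks of each list CTCF was enriched 408-fold and NRF1 6.63-fold, and 19 consensuses were called enriched, against 26 in the main setting. The calls of ETS (1.53), IRF (1.36), ERR (1.35), PBX-HOX (1.19), SOX (1.18), STAT (1.13), CAGATG (1.06) and FOX (1.02) ended there, and NFY was called (1.63).

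**Figure D2:**
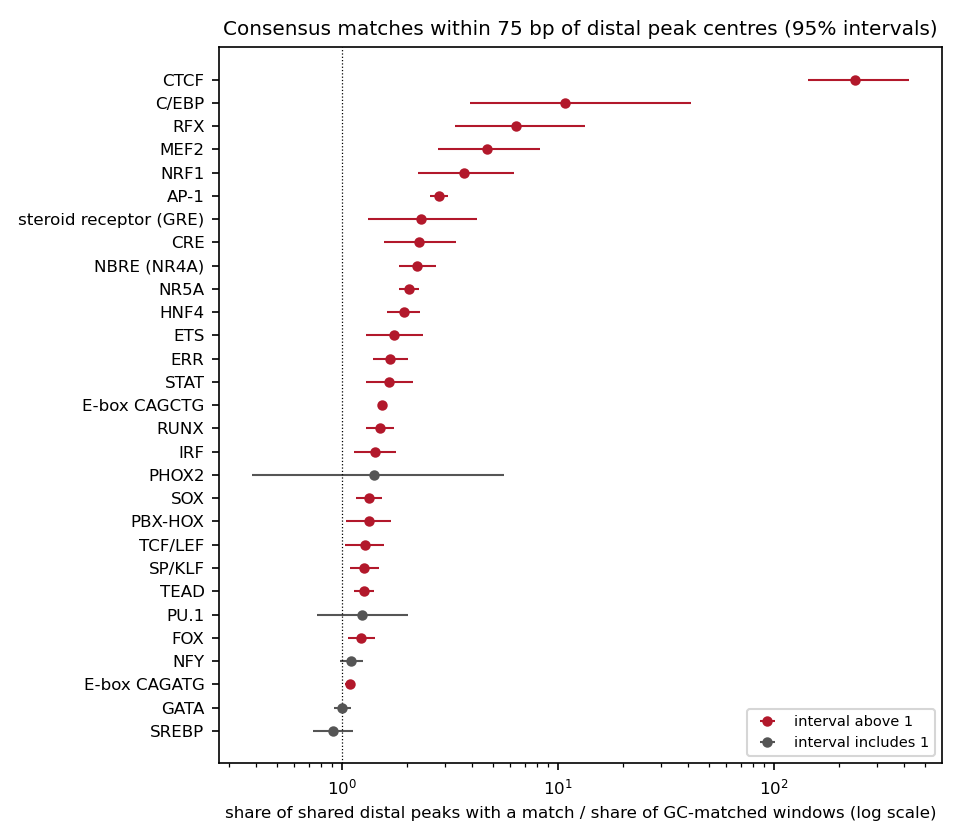
Enrichment of each consensus within 75 bp of the centres of 26615 shared distal peaks over GC-matched windows (x axis, fold on a log scale; bars are 95% intervals). Red points have intervals above 1, led by CTCF at 236-fold; consensuses with 0 matches in the windows, such as REST and NFI, are not drawn.

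Height ratios between the replicates differed by motif. Among shared distal peaks, with ratios centred within bins of height, those with an AP-1 match had a median log2 ratio of replicate 1 over replicate 2 that was 0.42 above that of peaks without one (95% bootstrap interval 0.39 to 0.45). The difference was 0.31 for NR5A (0.26 to 0.34), 0.38 for NFI, 0.36 for C/EBP and 0.25 for both NBRE and ERR. It was -0.28 for CTCF (-0.30 to -0.26) and -0.21 for REST (-0.32 to -0.12). Distal peaks found only in replicate 1 held an AP-1 match in 13.8% and an NR5A match in 7.62% of 39269 cases, against 6.21% and 3.96% of the shared ones, and a CTCF match in 2.71% against 13.3%. Of the 2434 distal peaks found only in replicate 2, 2.51% held an AP-1, 2.47% an NR5A and 2.59% a CTCF match.

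**Figure D3:**
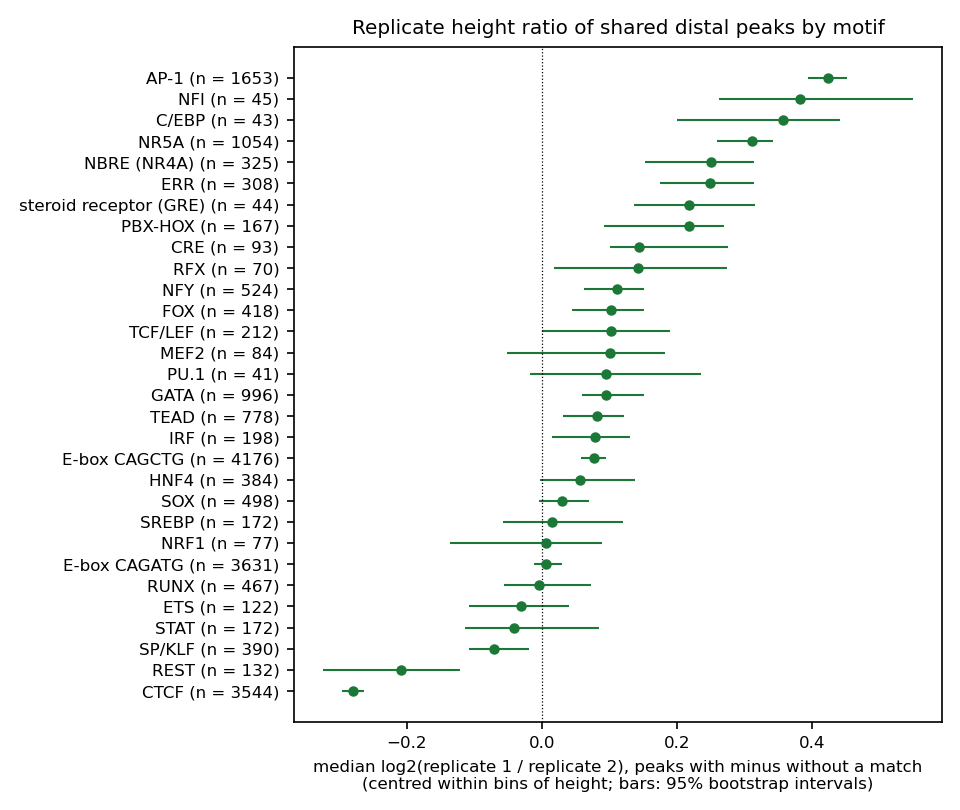
Difference in the median log2 ratio of peak heights, replicate 1 over replicate 2, between shared distal peaks with and without a match to each consensus (x axis, ratios centred within bins of height; bars are 95% bootstrap intervals over peaks). AP-1 lies highest at 0.42, NR5A at 0.31 and CTCF lowest at -0.28; consensuses with fewer than 20 peaks are not drawn.

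Footprints marked most CTCF, REST and NFI sites and a smaller share of nuclear receptor sites. Of 3564 CTCF matches in shared distal peaks, the centre of 95.8% lay in a footprint of replicate 1 and of 96.2% in one of replicate 2, against 50.3% and 45.4% for column-permuted versions of the consensus. REST matches were covered in 94.1% and 93.4% of 136 cases, with 0 permuted matches to compare, and NFI matches in 97.8% and 84.4% of 45 (permuted 29.3% and 24.4%). CRE was covered in 78.7% and 67.02% of 94 matches (permuted 28.0% and 23.5%). NR5A was covered in 50.8% of 1094 matches in replicate 1 (95% interval 47.8% to 53.8%) and 28.7% in replicate 2 (26.0% to 31.5%), against 21.7% and 19.5%, and AP-1 in 22.4% and 17.0%, against 16.1% and 15.9%. Coverage was above that of the permuted versions, with intervals apart, for 15 consensuses in replicate 1 and 9 in replicate 2, and these 9 were among the 15. It was below for the E-box CAGCTG and FOX in both replicates and for GATA in replicate 1. In promoter peaks, AP-1 in replicate 2 turned to 0.670 times the permuted share and PU.1 to 6.0 times.

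Single footprints agreed less than peaks. Of the replicate 1 footprints, 72.6% lay in that replicate's peaks and 34.4% overlapped a footprint of replicate 2. Of the replicate 2 footprints, 65.8% lay in its peaks and 49.5% overlapped one of replicate 1. Among all footprints, 23.8% of replicate 1 and 33.4% of replicate 2 met a 50% reciprocal overlap. Among footprints inside shared peaks, the overlap by at least 1 bp was 54.4% and 59.4%, against 27.0% and 28.9% after shifts within those peaks.

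Matches near adrenal genes were then listed, a step chosen after seeing the data. The promoter peak of Chga held the REST match TCAGCACCTCGGACAG at chromosome 12 102555239 to 102555254, and that of Chgb held TCAGCACCCCGGACAG at chromosome 2 132781795 to 132781810, each covered by a footprint in both replicates. The Scg2 promoter peak held the CRE TGACGTCA at chromosome 1 79440087 to 79440094, covered in both. No NR5A match lay in the highest shared promoter peak of a steroidogenesis gene. Such matches were rare at promoters, with 390 within 75 bp of the centres of 21677 shared promoter peaks. An absence in the peaks of 13 genes therefore says little. Among distal peaks, 4 with an NR5A match lay near 3 steroidogenesis genes. At Cyp11a1, TCAAGGCCA lay between genes at chromosome 9 57966032 to 57966040 (heights 2.85 and 1.30, footprint in both replicates) and in an intron at 58009145 to 58009153 (3.60 and 0.942, footprint in replicate 1). The others were near Fdx1 at chromosome 9 51991068 to 51991076, with a footprint in replicate 1, and in an intron near Por at chromosome 5 135708159 to 135708167, with none. Of 92 list and motif pairs computed, 8 were called higher. Lists with 0 NR5A, AP-1 or REST matches still stood at percentile 12.4 or above, so lower calls were hardly possible for these motifs. By peaks with a match per gene, NR5A was called near steroidogenesis (0.222 peaks per gene against 0.0607, percentile 97.9), glucocorticoid response (percentile 99.98), clock (99.3) and immediate early genes (97.6), AP-1 near immediate early (99.99) and clock genes (99.5), and CTCF and REST near brain neuron genes (99.8 each). These counts rise with the number of distal peaks, which was high near immediate early, glucocorticoid response and clock genes. The glucocorticoid response list also shared Per1 with the clock list and Dusp1 with the immediate early list. By peak, an NR5A match was held by 4 of 81 distal peaks near immediate early and 6 of 64 near glucocorticoid response genes. It was held by 5 of 63 near clock and 4 of 31 near steroidogenesis genes. An AP-1 match was held by 9 of 81 near immediate early and 6 of 63 near clock genes. Near brain neuron genes, 10 of 28 distal peaks held a CTCF match, and the REST call rested on 2 peaks. No test by peak was made.

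**Figure D4:**
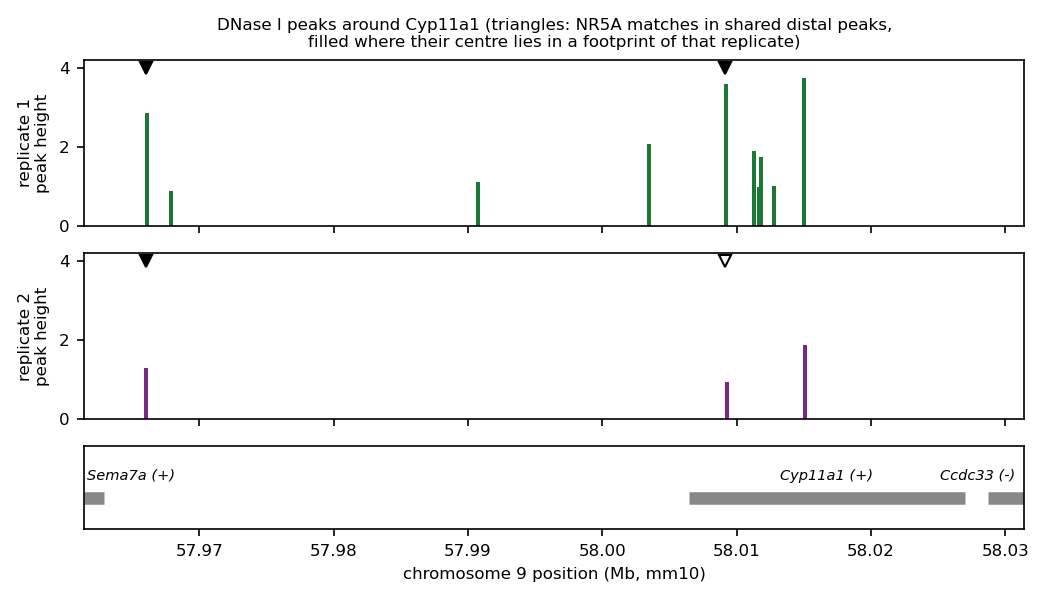
DNase I peaks of replicates 1 and 2 around Cyp11a1 (x axis, position on chromosome 9 in Mb, mm10; y axis, deposited peak height; grey bars are genes with strands, and narrow peaks are drawn wider than they are). Triangles mark the 2 NR5A matches in shared distal peaks, filled where a footprint of that replicate covers the match; replicate 1 has 10 peaks in the window and replicate 2 has 3.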

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

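The alternatives added after seeing the data were the overlap with any base under FDR 0.05, the centrings within bins of height, distal peaks only, genes with a promoter peak only and windows matched on CpG dinucleotides. Over 179 results, 792 values were computed under alternatives, and 633 were counted as the same. For single lists and motifs this meant the same call and direction, or no call in either setting whatever the direction. Counts of calls could differ by up to 1.5-fold. Other values had to stay within an interval, the middle 50% of peaks or the standard deviation of the 2 replicates. A direction was counted as reversed only where the result was called in the main or the alternative setting, and the cause of a change was not tested unless the setting itself shows it. Peak overlap was 40.3% of replicate 1 and 72.2% of replicate 2 with 50% reciprocal overlap, 42.3% and 75.7% with centres within 75 bp, 55.7% and 97.5% for the 50% highest peaks, 76.2% and 75.4% at equal list lengths, where the shorter list of replicate 2 no longer limits the overlap, and 78.1% and 97.7% with any base under FDR 0.05. With the longer lists 86.5% of replicate 2 overlapped. The Spearman correlation of heights across shared peaks was 0.890 in the 50% highest peaks. The promoter share ranged from 32.6% to 46.3% without a replicate. Of the promoter lists, 8 were higher and 7 lower without CpG matching, where cortex regulators stood at percentile 99.7, erythroid genes at 2.15 and steroidogenesis at 77.96. Lower lists numbered 5 at 500 bp, 5 with the most 5' start, where steroidogenesis stood at 97.2, and 6 in the 50% highest peaks, where chromaffin genes stood at 0.080, brain neuron genes at 0 and capsule genes at 35.2. Brain neuron genes were also lower at 500 bp (0.030) and with the most 5' start (0.21). Cholesterol genes were higher in the 50% highest peaks (98.7). For distal peaks, 5 lists were higher within 100 kb and 6 in the 50% highest peaks, and from 4 to 6 without a replicate, with steroidogenesis from percentile 80.8 to 99.9. For the replicate difference, 3 lists were higher and 2 lower with ranks, where brain neuron genes stood at 1.79 and zonation at 98.6, 2 lists were higher and 4 lower within 25 kb, and 0 and 5 within 100 kb, where steroidogenesis stood at 96.9. With distal peaks centred on height, 1 was higher (liver, 97.6) and 0 lower, on fewer genes and with wider random intervals. Steroidogenesis then had a median of 0.14 over 13 genes (percentile 87.8), against 0.19 over 18 with all peaks, chromaffin -0.11 over 20 (percentile 6.06), against -0.15 over 26, and cell cycle stood at 40.3. CTCF enrichment, 236-fold in the main setting, was 122.3-fold on replicate 1 alone and 137-fold on replicate 2 alone, and 148-fold against windows matched on GC and CpG content, where ETS lost its call (1.10). Against flanks, which were not matched on GC content, 5 motifs were depleted: GATA 0.670, PBX-HOX 0.755, FOX 0.784, TCF/LEF 0.789 and IRF 0.790. In the 50% highest peaks 19 were enriched, against 26, and 1 was depleted (SREBP, 0.611). Footprint overlap was 23.8% and 33.4% with 50% reciprocal overlap and 54.4% and 59.4% inside shared peaks. From 9 to 15 consensuses were covered above permuted ones without a replicate, and in promoter peaks of replicate 2 AP-1 stood at 0.670 and PU.1 at 6.0 times the permuted share. The counting error at the median height, 8.01% and 7.65% if each step was 1 tag, limits how well a single height is known and does not cover variation between animals or libraries. The myeloid list, at 0 of 15, could not be called lower because its random lists reached 0 as well, and the cholesterol, immediate early, cell cycle and housekeeping lists could not be called higher in the main setting because theirs reached 100%. No paired analysis was possible because there was 1 group.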

Other observations

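The library size test of the peak numbers was chosen after the result was seen, and the second adipocyte list, all ratios by motif and the centring on height were chosen after the data had been seen. The other tests were written before their results.

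A second list of 20 brown adipocyte genes, written before any of their values was seen, had shared promoter peaks at 14, among them Ppara (12.8 and 5.44), Ebf2 (8.40 and 3.53), Pank1 (5.595 and 3.00), Cox7a1 (5.49 and 3.20) and Gpd1 (4.198 and 2.76). Zic1, Tbx15, Cfd and Bmp8b had none.

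The adipocyte pattern was weighed against adipose tissue attached to the glands. The first list stood at 92.9% open promoters, but the second one, at 70.0% against 63.1% in matched lists, stood at percentile 80.8 and was not called. Attached fat therefore may explain the pattern but was not told apart from genes that the gland itself uses, and the number of list genes that adrenal cells also express was not tested. Height-centred ratios of replicate 1 over replicate 2 near the first list were lower than near random lists (-0.17, percentile 1.54). In the main setting the list was not called (5.78).

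Peaks near chromaffin genes had lower, and peaks near steroidogenesis genes higher, ratios of replicate 1 over replicate 2. A rise of the ratio with peak height cannot be the whole cause, since the difference was -0.34 after centring on height against -0.41 before. Against lists matched on the CpG content of the genes' own promoters, the chromaffin list stayed at percentile 0.55, which argues against that content as the whole cause. The CpG content of the other peaks within 50 kb was not matched. With distal peaks only, chromaffin (percentile 6.06) and steroidogenesis (87.8) were not called, on fewer genes. A smaller share of medulla against cortex in replicate 1 may contribute. Distal peaks with an NR5A match leaned to replicate 1 by 0.31 relative to those without one. The test asked only whether this value exceeded 0, so it does not single out this cause. Many other consensuses leaned the same way, such as NFI (0.38), C/EBP (0.36), the steroid receptor element (0.22) and PBX-HOX (0.22). Intervals below 0 were found only for CTCF, REST (-0.21) and SP/KLF (-0.07). The smaller share of medulla stays a hypothesis: AP-1 sites leaned further (0.42) and CTCF sites leaned the other way (-0.28). Brain neuron genes were called lower in all planned settings (percentiles from 0.090 to 1.79), though not with height centring (3.21). Adipocyte genes were called lower as well with height centring, though not in the planned settings (percentiles from 3.55 to 9.40). Schwann, endothelial and capsule lists stayed inside their random lists with height centring (percentiles 62.6, 44.5 and 24.6). In the main setting they stood at 19.7, 9.70 and 4.36, and within 100 kb the endothelial list was called lower (0.40) and the capsule list stood at 2.58. Dissection, age and animal differences between the samples were not tested.

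Replicate 1 had 1.79 times as many peaks as replicate 2. A larger sequenced library is argued against by the ratio of the totals that the height steps imply, 0.927, as far as the steps stand for single tags on 1 common scale. Of the peaks found only in replicate 1, 54.5% held a base at an FDR under 0.05 in replicate 2, against 1.93% after shifts, which is consistent with sites present in both samples but below the threshold in replicate 2. The other peaks stay open, and the lower heights of shared peaks in replicate 2 are what a lower signal over background would give, which was not tested on reads. The share of peaks 500 bp or wider was 1.72% in replicate 1 and 7.38% in replicate 2.

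A further test had been written for the highest distal peaks, on the premise that they had about the same height in both replicates. The premise did not hold for the top 20 as a set, since their median log2 ratio was 0.92 against 0.87 in the rest of the top decile. However, 8 of the 20 had a ratio under 0.5, against 17.4% of the rest. All 8 were among the 10 highest peaks, and from rank 11 to 20 no ratio lay below 0.858. The median over the top 20 therefore mixes these parts, and the premise held for most of the 10 highest peaks. For collapsed repeats in the reference, the share of soft-masked bases was 7.84% in the top 20 and 5.50% in the other 2642 peaks, a difference of 2.34 percentage points that leaves the cause open (one-sided permutation test, p = 0.115). This test took the 20 peaks together, so it does not answer for the 10 highest, which were not tested alone. Their shares ranged from 0% to 31.9%, and those of ranks 11 to 20 from 0% to 15.5%.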
